A study of Mus musculus with 27 samples.

How the data were processed

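Total RNA was extracted from cells of mouse foetal livers taken at embryonic day 14.5 and kept in culture for 0, 24 or 48 h in a serum-rich medium, then labelled with biotin and hybridized to Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols. The 27 arrays fall into 12 groups by genotype and culture time: wild type (WT), knockout of p107 (p107KO; the gene symbol of p107 is Rbl1), knockout of Rb1 (Rb1KO), and knockout of both (DKO). The genotypes hold 7, 5, 11 and 4 arrays in that order. The labels do not say whether the arrays of a group came from separate embryos or litters, so p-values measure only the spread between these samples, which may be technical. Which part of Rb1 or Rbl1 was altered is not given in the sources used here.

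The deposited values are MAS5 signal intensities on a linear scale, made by the authors with GCOS 1.4, per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of each probe set into a signal and scales each array. In the deposited table the mean signal without the highest and lowest 2% of probe sets lay between 491.9 and 497.7 on every array, so total brightness was made equal by the authors and the rest of the distribution was not. The array medians ran from 81.0 to 119.3, a ratio of 1.47 between the highest and the lowest. Detection calls, scanner images and control probe sets were not used here. Array data have no read depth, and the number of arrays limits the precision.

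Of the 45037 probe sets, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 were unnamed there. Only probe sets with 1 symbol were used, with symbols updated through Entrez identifiers where the gene table of assembly GRCm38.p6 allowed it (34741 probe sets matched). A gene with several probe sets was represented by the one with the highest mean, which gave 18193 genes. The 40% of genes with the lowest mean were left out, and 10916 genes were tested. Values were analysed as log2(signal + 32). The added 32 pulls fold changes of dim genes toward 0, and the folds of genes near the floor depend on it.

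Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 27 arrays, equal weights and a variance prior that follows brightness. This left 15 residual degrees of freedom, and the prior added 7.17. Groups with 1 array (p107KO at 48 h, DKO at 24 h and DKO at 48 h) thus borrow the spread of the other groups. Comparisons of genotypes gave each culture time the same weight. All adjusted p-values are Benjamini-Hochberg values from limma over the 10916 genes of a comparison, two-sided, with a threshold of 0.05. Errors beside log2 changes are standard errors (SE) from this fit. Gene lists were tested with limma's camera at its preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 31 lists tested. A list's count was also made with p-values adjusted over the list alone. Sex-linked genes form a further list, used as a description of the arrays and not tested as a set.

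The groups, 16 comparisons, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text may name Rb1, Rbl1 and Rbl2; the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold whose higher group is brighter than the median gene and whose arrays do not overlap between the groups at any time compared; and up to 4 members of each list with the smallest adjusted p. Exceptions are said to have been chosen after their values were seen. Hspa1a and Hspa1b are near-identical copies, so their probe sets may read both and their separate values are uncertain.

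The scripts' steps were tested on simulated data in which 100 genes of 10916 changed 2-fold and 100 changed 4-fold. For Rb1KO against WT averaged over time, 94% of the 2-fold and 100% of the 4-fold genes were recovered. At single times the shares for 2-fold genes were 77% at 0 h, 58% at 24 h and 50% at 48 h. For p107KO against WT averaged over time they were 86% and 100%, and for DKO against Rb1KO also 86% and 100%. The simulated noise was independent between arrays and had the same spread on each array for a gene. It held no sex difference, shared deviation or outlying array, so these shares may overstate recovery in the real data. Alternatives tried were pseudocounts of 1 and 100, no filter or a filter at 60%, quantile normalization, the mean over a gene's probe sets, array weights, only the arrays of the groups compared, the replicate number as a block, and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.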

Results

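The series measured gene expression in E14.5 mouse foetal liver cells, a stage at which the liver is the main site of red cell production, as they were cultured for 0, 24 and 48 h. It compared wild-type cells with cells lacking the pocket proteins Rb1 or p107 (gene Rbl1), which bind E2F transcription factors and restrain entry into S phase, or lacking both. WT had 3, 2 and 2 arrays at 0, 24 and 48 h, p107KO had 2, 2 and 1, Rb1KO had 5, 4 and 2, and DKO had 2, 1 and 1. Culture time set the largest differences between arrays: the first principal component held 61.1% of the variance and placed all 0 h arrays between -68.6 and -52.1 and all cultured arrays between 36.3 and 60.9. The second component held 12.5% and ran from -15.7 or above in the WT and p107KO arrays at 24 h to -28.4 or below in the Rb1KO and DKO arrays of that time. Of the 0 h and 24 h arrays, 4 had the lowest correlation across genes with other arrays of their time (median r 0.937 to 0.954). These were Rb1KO 0 h replicate 5 and replicate 1 of Rb1KO, p107KO and DKO at 24 h, called the 4 arrays apart below. In the 3 at 24 h the brightest probe set reached 125649 to 154046, against at most 90606 in the other 24 arrays. Rb1KO 24 h replicate 4 followed with a median r of 0.956, and Rb1KO 48 h replicate 2 gave 0.943. The correlation alone thus does not set the 4 apart from all other arrays. None of the 4 belongs to the groups of Rb1KO against WT at 48 h or of DKO against WT at 0 h. Leaving them out changes those counts only through the spread estimated over all arrays.

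**Figure D1:**
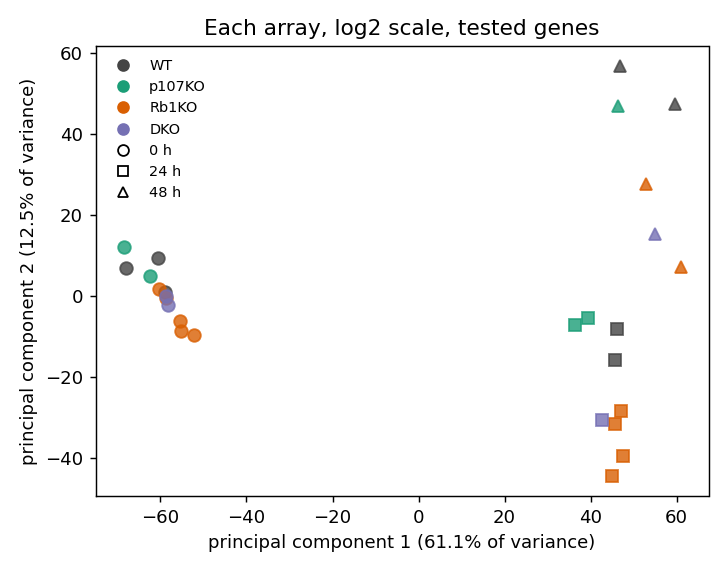
Principal components of the 27 arrays on the log2 scale; colour gives the genotype, and circles, squares and triangles give 0, 24 and 48 h of culture. Component 1 (61.1% of the variance) separates 0 h from cultured arrays, and component 2 (12.5%) separates 24 h from 48 h.

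The targeted genes were examined first. Rbl1 was nearly lost in arrays labelled as lacking p107: its brightest probe set gave a signal of 1619 ± 110 (SD, n = 3) in WT at 0 h and 112.9 ± 6.01 (SD, n = 2) in p107KO, and 85.9 ± 1.98 (SD, n = 2) in DKO. Averaged over the culture times, Rbl1 was 9.25-fold lower in p107KO than in WT (log2 -3.21 ± 0.16 SE, limma adjusted p = 1.80e-11). The brightest Rb1 probe set gave 6609 ± 482 (SD, n = 3) in WT at 0 h against 2109 ± 481 (SD, n = 5) in Rb1KO and 1520 ± 202 (SD, n = 2) in DKO. The Rb1KO deficit was 3.16-fold at 0 h (log2 -1.66 ± 0.18 SE, limma adjusted p = 1.17e-05) and 2.58-fold at 24 h (log2 -1.37 ± 0.21 SE, limma adjusted p = 0.000208). At 48 h the 2 arrays labelled Rb1KO gave 4830 ± 881 (SD, n = 2), the array labelled DKO gave 5994, and WT gave 6164 ± 592 (SD, n = 2). The 48 h difference between Rb1KO and WT did not pass (log2 -0.36 ± 0.24 SE, limma adjusted p = 0.410), and the change of the difference from 0 h to 48 h did (log2 1.30 ± 0.30 SE, limma adjusted p = 0.0143), though not without WT 48 h replicate 1 (adjusted p = 0.0679) or Rb1KO 48 h replicate 2 (adjusted p = 0.145). So at 48 h the Rb1 probe set does not check the labels, and whether it lies in the altered part of the gene is not given in the sources used here. A second Rb1 probe set was dim and moved the other way, at 133.7 ± 28.3 (SD, n = 4) in Rb1KO and 35.0 ± 43.8 (SD, n = 2) in WT at 24 h. Taking the mean over both probe sets turned the 24 h difference to 0.048 on the log2 scale (limma adjusted p = 0.933). Rbl1 itself rose 1.47-fold in Rb1KO against WT over the culture times (log2 0.56 ± 0.14 SE, limma adjusted p = 0.00525), whereas Rbl2, the related pocket protein p130, gave -0.073 ± 0.17 (SE, limma adjusted p = 0.806).

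**Figure D2:**
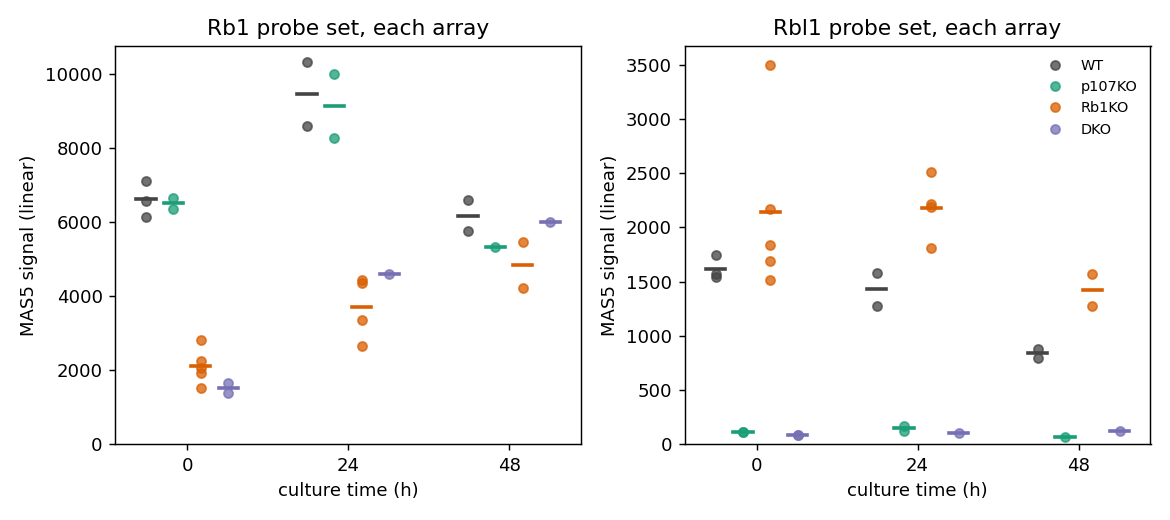
MAS5 signal (linear) of the Rb1 and Rbl1 probe sets in each array against culture time in hours; points are arrays, offset by genotype, and bars are group means. Rb1 in Rb1KO arrays rises from a mean of 2109 at 0 h to 4830 at 48 h, while Rbl1 in p107KO and DKO arrays stays at or below 167.5.

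Sex-linked genes differed between the genotypes. Eif2s3y and Kdm5d, on the Y chromosome, gave signal in 0 of 7 WT, 2 of 5 p107KO, 3 of 11 Rb1KO and 4 of 4 DKO arrays. Eif2s3y ran from 762.5 to 2665 in these 9 arrays and from 0.70 to 31.3 in the others, and Xist, which coats the inactive X chromosome in females, ran from 83.9 to 223.4 and from 1656 to 16439. Comparisons of DKO with WT therefore also compare arrays with and without a Y chromosome.

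In Rb1KO against WT averaged over the culture times (11 and 7 arrays), most of the listed genes of DNA replication and mitosis rose. Zfp367, a zinc finger gene, rose 5.29-fold (log2 2.40 ± 0.10 SE), Ccne2 (cyclin E2, which drives entry into S phase) 2.86-fold (log2 1.52 ± 0.15 SE), and Slbp, which binds histone messages, 2.14-fold (log2 1.10 ± 0.07 SE, limma adjusted p = 7.78e-10). Larger rises were those of the inducible heat shock proteins Hspa1b (9.47-fold, log2 3.24 ± 0.18 SE) and Hspa1a (6.89-fold, log2 2.78 ± 0.18 SE), whose probe sets may read both genes, and of the noncoding gene Dleu2 (7.09-fold, log2 2.83 ± 0.13 SE), which shares a chromosome with Rb1. Fgf13 (5.03-fold), the deubiquitinase Otud1 (3.93-fold) and the transcription factor Klf5 (2.93-fold) also rose. Tcp11l2 fell by 1.34 ± 0.10 (SE) on the log2 scale, 2.53-fold, and Bpgm, the red cell enzyme that makes 2,3-bisphosphoglycerate, fell 2.02-fold (log2 -1.01 ± 0.13 SE, limma adjusted p = 4.11e-06).

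Of 56 measured E2F-regulated genes of G1/S and DNA replication, 40 rose and 1 fell (43 and 2 adjusted over the list alone), with a median log2 change of 0.50 (camera adjusted p = 1.59e-25, and adjusted p = 0.00161 with an estimated correlation). Clspn (log2 1.07 ± 0.09 SE), a checkpoint mediator at replication forks, Asf1b (1.12 ± 0.10 SE), a histone chaperone, and Prim1 (0.88 ± 0.08 SE), the primase subunit, were among them. The 1 that fell was E2f3 (log2 -0.35), named after its value was seen. Of 51 genes of G2/M and mitosis, 31 rose and 0 fell (34 and 0 adjusted over the list alone, median 0.38, adjusted p = 0.0113 with an estimated correlation). Among them were Racgap1 (0.97 ± 0.10 SE), needed for cytokinesis, Tpx2 (0.72 ± 0.07 SE), a spindle assembly factor, and Cdk1 (0.65 ± 0.08 SE). Of 25 DNA damage repair genes 7 rose and 0 fell (7 and 0 adjusted over the list alone), Brca1 by 0.90 ± 0.10 (SE), with an adjusted p = 0.572 with an estimated correlation.

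Some markers of other blood lineages fell, in lists whose calls were lost with an estimated correlation. Of 21 megakaryocyte and platelet markers, 12 fell and 0 rose (16 and 0 adjusted over the list alone), with a median log2 change of -0.52 and an adjusted p = 0.510 with an estimated correlation. Plek (-0.67 ± 0.13 SE), the integrin Itgb3 (-0.64 ± 0.15 SE) and Gp1bb (-0.57 ± 0.14 SE) were among them. Of 20 stem and progenitor markers 4 fell and 0 rose, led by Mllt3 (-1.20 ± 0.13 SE) and Slamf1 (-0.54 ± 0.15 SE; list adjusted p = 0.403 with an estimated correlation, 4 adjusted over the list alone). Of 18 neutrophil and granulocyte markers 2 fell (1 adjusted over the list alone; adjusted p = 0.751 with an estimated correlation).

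Genes of the red cell lists moved both ways. Of 27 genes of late erythroid clearance, a list of autophagy, ubiquitin and enucleation genes, 9 fell and 2 rose (11 and 3 adjusted over the list alone; median -0.18, adjusted p = 0.572 with an estimated correlation). Ube2o, which remodels the reticulocyte proteome, fell by 1.27 ± 0.13 (SE) on the log2 scale, the autophagy receptor Sqstm1 by 0.67 ± 0.10 (SE) and the ubiquitin-conjugating enzyme Ube2h by 0.69 ± 0.10 (SE), while the autophagy kinase Ulk2 rose (0.75 ± 0.13 SE). Of 21 adult globin and membrane genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.751 with an estimated correlation). The adhesion molecule Icam4 was at 1.04 ± 0.13 (SE) and Xk at -0.81 ± 0.14 (SE). Gfi1b, a transcription factor of red cells and platelets, rose by 1.18 ± 0.19 (SE). Of 14 heat shock genes 4 rose and 3 fell (4 and 4 adjusted over the list alone; adjusted p = 0.572 with an estimated correlation). Besides Hspa1a and Hspa1b, Dnajb1 (1.00 ± 0.12 SE) and Hsp90aa1 (0.58 ± 0.12 SE) rose. The mitochondrial chaperones Hspd1 (-0.33 ± 0.11 SE) and Hspe1 (-0.32 ± 0.10 SE) were among those that fell. The CDK inhibitor Cdkn2c (1.20 ± 0.10 SE), the histone variant H2ax (0.82 ± 0.11 SE) and the cell death gene Bcl2l11 (1.00 ± 0.14 SE) rose as well. Of 39 oxidative phosphorylation genes 3 fell and 0 rose (0 adjusted over the list alone; adjusted p = 0.751 with an estimated correlation).

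In all, 2062 of 10916 genes passed in this comparison, 1127 higher and 935 lower, and 109 and 27 of them by 2-fold or more. The count was 1329 without Rb1KO 48 h replicate 2, 685 without the 48 h arrays, and 1032 without the 9 arrays with Y-linked signal, the latter 2 chosen after seeing the data. The same contrast on separate arrays, DKO against p107KO, was set beside it after the data were seen. Y-linked signal was more frequent on the side lacking Rb1 in both (3 of 11 against 0 of 7, and 4 of 4 against 2 of 5 arrays). Both also share 1 estimate of the spread, so a sex difference could add to the overlap. Of the 2062 genes, 1933 (93.7%) had the same sign in DKO against p107KO. Of the 764 genes past the threshold there (217 without p107KO 48 h replicate 1, 222 and 362 without DKO 48 h or 24 h replicate 1), 631 were also among the 2062, all 631 in the same direction. Of these 444 were higher and 187 lower, against 49.7 and 24.2 for independent lists.

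At 0 h (5 Rb1KO and 3 WT arrays) few genes differed, and heat shock genes were among them. Hspa1b was 7.12-fold higher (log2 2.83 ± 0.25 SE) and Hspa1a 5.18-fold (2.37 ± 0.26 SE), and Dnajb1 rose by 0.84 ± 0.18 (SE). The p53 targets Trp53inp1 (2.68-fold, log2 1.42 ± 0.15 SE), Cdkn1a, the CDK inhibitor p21 (2.45-fold, 1.29 ± 0.21 SE), and Bbc3, the cell death activator PUMA (2.27-fold, 1.19 ± 0.21 SE), rose, as did the immediate early gene Fos (3.14-fold, 1.65 ± 0.24 SE). Klf5 (2.72-fold) and Ccne2 (2.48-fold) were higher, and Epor, the erythropoietin receptor (log2 -0.97 ± 0.20 SE, limma adjusted p = 0.0211), Ube2o, Mllt3 and Tcp11l2 were lower. Of the 14 heat shock genes 3 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.0201 with an estimated correlation). The E2F list had 2 that rose and 0 that fell (7 and 0 adjusted over the list alone; median 0.18, adjusted p = 0.0454 with an estimated correlation). The G2/M list had 0 and 0 with a median of 0.21 (limma camera adjusted p = 2.13e-11 for the list, adjusted p = 0.0518 with an estimated correlation). Calls lost with an estimated correlation were those of p53 targets (3 rose of 26, adjusted p = 0.0615), CDK inhibitors (3 of 21, adjusted p = 0.0615), immediate early genes (2 of 21, adjusted p = 0.112) and megakaryocyte markers (median -0.46, adjusted p = 0.112). In limma 67 genes passed, 59 higher and 8 lower. The count was 26, 26 and 38 without WT 0 h replicate 1, 2 or 3. It was 32 with only these groups in the fit, 166 with array weights and 27 without arrays with Y-linked signal.

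At 24 h (4 Rb1KO and 2 WT arrays) Dleu2 and Hspa1b were among the higher genes and Crem and Fabp4 among the lower. Dleu2 was 15.7-fold higher (log2 3.97 ± 0.23 SE), Hspa1b 15.8-fold (3.98 ± 0.30 SE), Fgf13 6.00-fold (2.59 ± 0.28 SE), Ccne2 2.91-fold, Slbp 1.84-fold and Racgap1 1.97-fold. Crem, a cAMP-responsive transcription factor, was 5.75-fold lower (log2 -2.52 ± 0.23 SE), the fatty acid binding protein Fabp4 7.08-fold, the chemokine receptor Ackr3 5.92-fold and the death ligand Fasl 5.08-fold. Gadd45a, a growth arrest gene, was 2.49-fold lower, and Hmox1, which breaks down heme, 4.06-fold. Of the 56 E2F genes 17 rose and 1 fell, E2f3 again (25 and 1 adjusted over the list alone; median 0.35, adjusted p = 0.0550 with an estimated correlation). In the G2/M list 8 of 51 rose and 0 fell (12 and 0 adjusted over the list alone; adjusted p = 0.254 with an estimated correlation). Interferon response genes rose in 4 of 27 cases and fell in 0 (6 and 0 adjusted over the list alone; adjusted p = 0.661 with an estimated correlation), with Stat2 at 1.45 ± 0.29 (SE) and Usp18 at 1.11 ± 0.34 (SE). Mast cell and basophil markers had a median of -0.55, with 1 of 8 past the threshold (adjusted p = 0.661 with an estimated correlation). In limma 833 genes passed, 453 higher and 380 lower. The count fell to 361 and 297 without WT 24 h replicate 1 or 2. It was 273 with only these groups in the fit, 538 without arrays with Y-linked signal and 1335 without the 4 arrays apart, a choice made after seeing the data.

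At 48 h (2 arrays each) most of the E2F-regulated genes and part of the G2/M genes were higher in Rb1KO than in WT. Zfp367 was 12.2-fold higher (log2 3.60 ± 0.20 SE), the ATP-gated channel P2rx7 10.6-fold (3.40 ± 0.33 SE), the recombination protein Rad51c 9.32-fold (3.22 ± 0.27 SE), Dleu2 11.5-fold, E2f8, an E2F repressor, 4.34-fold (2.12 ± 0.21 SE) and Slbp 3.86-fold (1.95 ± 0.15 SE). Of the 56 E2F genes 39 rose and 0 fell (43 and 0 adjusted over the list alone; median 0.93, adjusted p = 0.000512 with an estimated correlation). Likewise 24 of the 51 G2/M genes rose and 0 fell (35 and 0 adjusted over the list alone; median 0.75, adjusted p = 0.00963 with an estimated correlation). Asf1b (2.04 ± 0.20 SE), Racgap1 (1.77 ± 0.19 SE) and Brca1 (1.83 ± 0.20 SE) were among them or among the 8 of 25 repair genes that rose (adjusted p = 0.455 with an estimated correlation; 11 adjusted over the list alone). The red cell genes Icam4 (4.45-fold), Gfi1b (4.69-fold) and Cpox, an enzyme of heme synthesis (3.46-fold), were higher. Cish, a feedback inhibitor of cytokine signalling, was 3.48-fold lower (log2 -1.80 ± 0.20 SE) and Hmox1 3.86-fold lower. Of 27 hepatocyte markers, with a median of -1.09, 4 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 0.720 with an estimated correlation). Rbp4 (-1.94 ± 0.55 SE), Fgb (-1.71 ± 0.48 SE) and Itih2 (-1.45 ± 0.40 SE) were among those that fell. These 3 did not pass without WT 48 h replicate 1 (limma adjusted p = 0.392, 0.419 and 0.202) or without Rb1KO 48 h replicate 2 (adjusted p = 0.449, 0.449 and 0.515). The hepatocyte marker mean was 9.02 and 7.63 on the log2 scale in the WT arrays and 8.01 and 6.90 in Rb1KO, so the difference depends on single arrays of both groups. In limma 1132 genes passed, 814 higher and 318 lower. The count was 638 without WT 48 h replicate 2, 477 without Rb1KO 48 h replicate 2, 595 with only these groups, 297 without arrays with Y-linked signal and 1720 without the 4 arrays apart.

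Tests of the genotype-by-time interaction asked whether the Rb1KO difference changed during culture. From 0 h to 48 h it grew for the E2F list, in which 18 of 56 genes had a larger difference and 0 a smaller one (33 and 0 adjusted over the list alone; median 0.72, adjusted p = 0.00185 with an estimated correlation). Tyms, which makes thymidylate, gave 2.36 ± 0.33 (SE), Ccne1 (cyclin E1) 1.79 ± 0.27 (SE), Asf1b 1.68 ± 0.24 (SE) and Racgap1 1.61 ± 0.24 (SE). Slbp gave 1.48 ± 0.18 (SE), and its probe sets disagree in direction here. P2rx7 gave 3.55 ± 0.41 (SE) and Icam4 2.09 ± 0.32 (SE). The p53 targets Trp53inp1 (-1.47 ± 0.25 SE), Bbc3 (-1.53 ± 0.36 SE) and Cdkn1a (-1.43 ± 0.36 SE), higher in Rb1KO at 0 h, gave negative values. In that list 3 of 26 genes passed, all lower (9 lower and 1 higher adjusted over the list alone; median -0.40, adjusted p = 0.0447 with an estimated correlation). In limma 380 genes passed, 290 higher and 90 lower. The count was 197 without WT 48 h replicate 2, 128 without Rb1KO 48 h replicate 2, 42 without arrays with Y-linked signal and 700 without the 4 arrays apart. From 0 h to 24 h 90 passed, 35 higher and 55 lower, with Dleu2 at 2.99 ± 0.30 (SE), Apold1 at 2.56 ± 0.33 (SE), Fasl at -3.33 ± 0.46 (SE), Ackr3 at -3.16 ± 0.42 (SE) and Cish at -1.19 ± 0.23 (SE). That count was 49, 52 and 54 without WT 0 h replicate 1, 2 or 3, and 53 (32 higher and 21 lower) and 44 without WT 24 h replicate 1 or 2. With the mean over probe sets 49 were higher and 42 lower. It was 55 with only these groups, 28 without arrays with Y-linked signal, 168 without the 4 arrays apart and 196 with array weights.

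Few genes differed between p107KO (5 arrays) and WT (7 arrays). Averaged over the culture times 2 genes passed in limma, Rbl1 itself and Zbtb32, a transcriptional repressor of lymphoid cells, which was 4.27-fold lower (log2 -2.10 ± 0.28 SE, limma adjusted p = 0.000943). At 0 h Rbl1 alone passed, 11.4-fold lower. At an unadjusted p under 0.05 the counts were 708 and 71. Among the lists, Rbl1 in the E2F list was the 1 member past the threshold over all genes in each comparison, and over time the set test placed late erythroid clearance (median -0.20), p53 targets (median -0.23) and CDK inhibitors (median -0.13) below other genes, each with an adjusted p = 0.0342 with an estimated correlation. Hepatocyte markers (median 0.53) and interferon response genes (median 0.33) lay above other genes only at the preset correlation (adjusted p = 0.396 for each with an estimated correlation). At 0 h the set calls for cholesterol synthesis (median 0.19), the unfolded protein response (0.17) and interferon genes (0.34) were likewise lost, with an adjusted p = 0.349, 0.289 and 0.528 with an estimated correlation. The count of 2 was 4, 10 and 15 without WT 24 h replicate 1, p107KO 24 h replicate 2 or WT 48 h replicate 1, 9 with array weights, and 1 with the mean over probe sets.

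In DKO against WT (4 and 7 arrays, averaged over the culture times) most genes of the E2F and G2/M lists rose and some genes of late erythroid clearance fell. Hspa1b was 16.6-fold higher (log2 4.05 ± 0.23 SE), Hspa1a 10.9-fold (3.45 ± 0.23 SE), Dleu2 7.19-fold (2.85 ± 0.17 SE) and Zfp367 5.51-fold (2.46 ± 0.13 SE). Tcp11l2 was 5.12-fold lower (log2 -2.36 ± 0.12 SE, limma adjusted p = 2.10e-11), the membrane protein gene Serinc3 4.11-fold and Bpgm 3.49-fold, and Gadd45a 2.86-fold. Of the 56 E2F genes 36 rose and 1 fell, the targeted Rbl1 itself (45 and 1 adjusted over the list alone; median 0.53, adjusted p = 0.00393 with an estimated correlation). Examples were Slbp at 0.98 ± 0.10 (SE), Asf1b at 1.18 ± 0.13 (SE) and E2f8 at 1.19 ± 0.13 (SE). Of the 51 G2/M genes 33 rose and 0 fell (41 and 0 adjusted over the list alone; median 0.58, adjusted p = 0.00476 with an estimated correlation), for example Racgap1 at 1.25 ± 0.13 (SE) and Cdk1 at 0.83 ± 0.10 (SE). Late erythroid clearance genes fell in 8 of 27 cases and rose in 0 (13 and 0 adjusted over the list alone; median -0.30, adjusted p = 0.0280 with an estimated correlation). Ube2o fell by 3.74-fold, Ube2h by 2.39-fold, Sqstm1 by 2.35-fold and Fbxo30 by 2.27-fold. Interferon response genes rose in 11 of 27 cases and fell in 1, Rsad2 (16 and 1 adjusted over the list alone; adjusted p = 0.473 with an estimated correlation), with Bst2 at 1.57 ± 0.29 (SE) and Stat2 at 1.05 ± 0.22 (SE). Macrophage markers fell in 2 of 26 cases (adjusted p = 0.735 with an estimated correlation). Eif2s3y was higher and Xist lower, at the signals given above. In limma 1457 genes passed, 863 higher and 594 lower. The count was 884 without DKO 24 h replicate 1, 448 without DKO 48 h replicate 1 (217 higher and 231 lower), and 456 without the 48 h arrays (227 and 229). It was 609 with Y-linked signal as a covariate, 2242 with array weights and 2278 with only these groups.

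At 0 h (2 DKO and 3 WT arrays) some heat shock and immediate early genes were again higher. Hspa1b was 11.7-fold higher (log2 3.55 ± 0.32 SE), Hspa1a 7.64-fold, Fos 3.16-fold, Cdkn1a 2.95-fold and Zfp367 2.69-fold, and Trp53inp1 rose by 0.97 ± 0.19 (SE) on the log2 scale. Tcp11l2 was 3.60-fold lower and the interferon-induced Rsad2 2.76-fold lower, beside Rb1 (4.29-fold) and Rbl1 (14.0-fold). The heat shock list (2 of 14 rose, 3 adjusted over the list alone, adjusted p = 0.00887 with an estimated correlation) and the immediate early list (2 of 21 rose, 2 adjusted over the list alone, adjusted p = 0.0183 with an estimated correlation) passed as sets. In limma 20 genes passed, 14 higher and 6 lower. The count was 10 without WT 0 h replicate 1, 9 and 7 without DKO 0 h replicate 1 or 2, 9 with Y-linked signal as a covariate, 44 with quantile normalization, 53 without the 4 arrays apart, 149 with only these groups and 392 with array weights.

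DKO against Rb1KO (4 and 11 arrays) asked what loss of p107 adds when Rb1 is absent. Rbl1 was 14.0-fold lower (log2 -3.81 ± 0.17 SE). Some late erythroid clearance genes were lower again, 5 of 27 falling and 0 rising (10 and 0 adjusted over the list alone; median -0.26, adjusted p = 0.0420 with an estimated correlation). Among them were Fbxo30 (-0.62 ± 0.13 SE), Sqstm1 (-0.56 ± 0.12 SE) and Ube2h (-0.56 ± 0.13 SE). The list test was not repeated with arrays left out, so this call was not checked against the lone DKO arrays at 24 h and 48 h. Tcp11l2 (-1.02 ± 0.12 SE), Bpgm (-0.79 ± 0.15 SE), Gadd45a (-0.71 ± 0.13 SE), Serinc3 (-1.93 ± 0.39 SE) and the X-linked demethylase Kdm5c (-0.79 ± 0.17 SE) were lower. Y-linked signal was present in 4 of 4 DKO and 3 of 11 Rb1KO arrays, so for Kdm5c sex cannot be told apart from loss of p107. Whether genes beside Rbl1 were called more often was not tested here. A segment of another strain beside the altered Rbl1 gene thus stays open for the genes called. The progenitor markers Cd34 (0.87 ± 0.15 SE), Sox4 (0.70 ± 0.15 SE) and Spn (0.60 ± 0.14 SE) were higher, 3 of 20 in that list (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.416 with an estimated correlation), and so were the DNA methyltransferase Dnmt3b (0.82 ± 0.16 SE) and the interferon-induced Ifitm3 (0.86 ± 0.16 SE) and Iigp1 (0.95 ± 0.21 SE). Interferon response genes had a median of 0.58 with 0 of 27 past the threshold over all genes and 16 adjusted over the list alone (adjusted p = 0.241 with an estimated correlation). Of the 56 E2F genes 0 rose and 1 fell, the targeted Rbl1 (1 and 2 adjusted over the list alone), and the set test gave no call (median 0.022, mean -0.024, camera adjusted p = 0.983). The G2/M call (median 0.17) was lost (adjusted p = 0.416 with an estimated correlation). Adult globin and membrane genes (median -0.24) and heme and iron genes (median -0.10) also lost their calls (adjusted p = 0.361 and 0.416 with an estimated correlation).

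In limma 109 genes passed for DKO against Rb1KO, 65 higher and 44 lower (48 and 59 with quantile normalization, 34 and 52 with the mean over probe sets). The number was 2 without DKO 24 h replicate 1, 13 and 20 without DKO 0 h replicate 1 or 2, 63, 56 and 256 without Rb1KO 0 h replicate 1, 2 or 5, 170 without Rb1KO 24 h replicate 1, and 33 and 55 without Rb1KO 48 h replicate 1 or 2. It was 4 with Y-linked signal as a covariate, 689 with array weights and 18 with only these groups. The interaction of the Rb1 and p107 genotypes, which asks whether the DKO differs from the sum of both single losses, gave 0 genes in limma and 495 at an unadjusted p under 0.05. Its set calls, of which hepatocyte markers had the largest median (-0.78), were lost with an estimated correlation (adjusted p = 0.638 for that list).

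**Figure D3:**
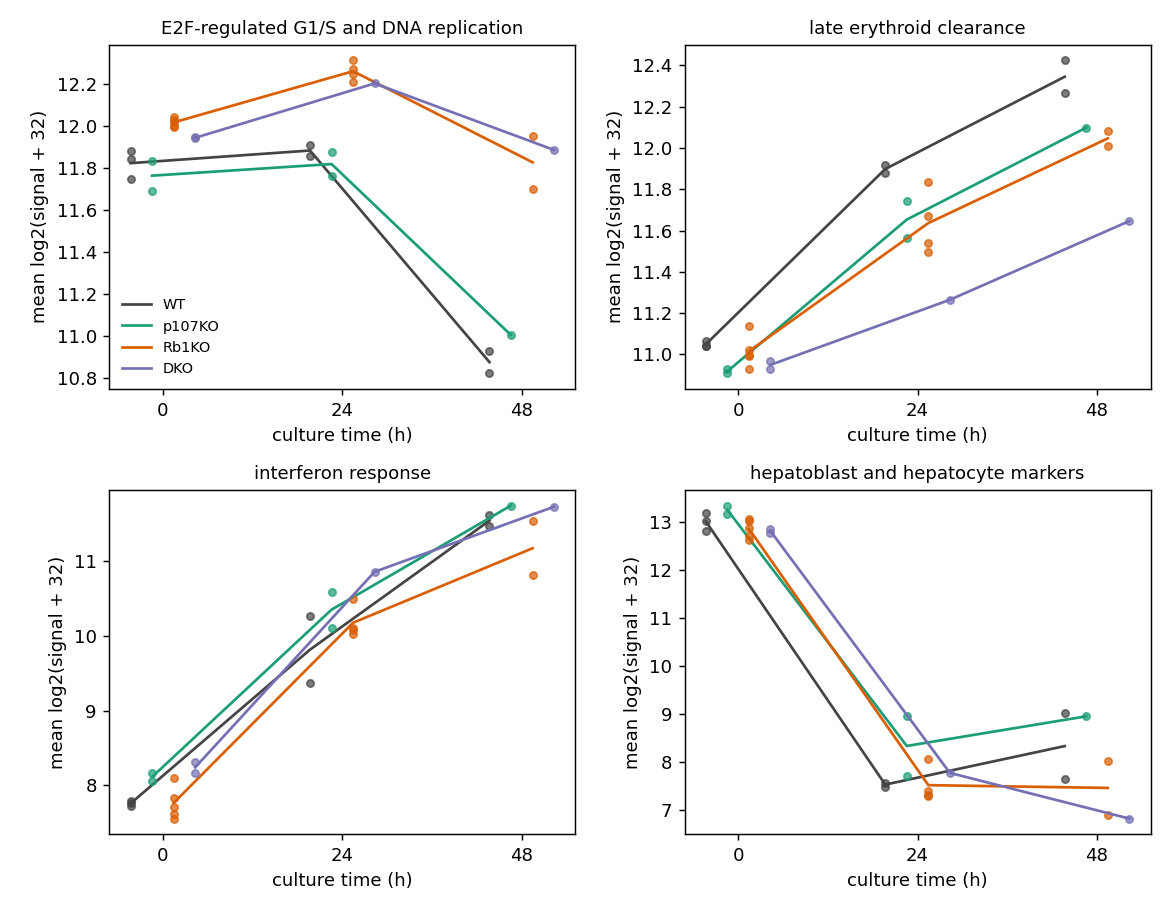
Mean log2(signal + 32) over the measured genes of 4 lists against culture time in hours; points are arrays, offset by genotype, and lines join group means. The WT mean of the E2F list drops between 24 and 48 h and Rb1KO and DKO arrays stay higher. Late erythroid clearance genes rise in all genotypes and least in DKO, which has 1 array at 24 h and 1 at 48 h. Interferon genes rise and hepatocyte markers fall in all genotypes.

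Many genes differed between culture times in the WT arrays. The arrays read a mixture of liver cells, so they cannot tell a change within cells from a change in the mix of cells. This limit holds for all comparisons of culture times and of genotypes, including those given above. After 24 h (2 against 3 arrays) liver markers had fallen: all 27 hepatoblast and hepatocyte markers fell, with a median log2 change of -6.40 (adjusted p = 0.0321 with an estimated correlation). Serpina6 fell by 459-fold, Fgg by 230-fold, Apoa1 by 158-fold and Dlk1 by 116-fold. Mesenchymal markers fell in 16 of 18 cases (16 adjusted over the list alone; median -3.64, adjusted p = 0.0209 with an estimated correlation), Col3a1 by 43.4-fold and Col1a1 by 28.2-fold. Endothelial markers fell in 14 of 15 cases (15 adjusted over the list alone; median -2.09, adjusted p = 0.0163 with an estimated correlation), Lyve1 by 46.6-fold and Stab2 by 14.1-fold. The resident macrophage genes C1qa (log2 -4.47 ± 0.57 SE) and Mrc1 (-3.42 ± 0.25 SE) and the progenitor receptor Kit (-1.82 ± 0.28 SE) fell, while Acod1 (5.83 ± 0.33 SE) and Clec4d (4.84 ± 0.37 SE), of activated myeloid cells, rose. The p53 targets Cdkn1a (54.7-fold), Trp53inp1 (16.2-fold), Ccng1 (12.3-fold) and Bbc3 (6.09-fold) rose, 13 of 26 up and 3 down (15 and 3 adjusted over the list alone; adjusted p = 0.0163 with an estimated correlation). So did 18 of 27 late erythroid clearance genes, with 0 down (19 and 0 adjusted over the list alone; adjusted p = 0.0209 with an estimated correlation), Sqstm1 by 3.81-fold and Gabarapl1 by 2.79-fold. The stress regulators Trib3 (44.2-fold) and Ddit3 (13.1-fold) and the immediate early genes Jun (8.03-fold) and Fos (9.34-fold) rose too. Interferon response genes rose in 20 of 27 cases, Ifit1 by 78.2-fold and Usp18 by 17.9-fold (21 adjusted over the list alone; adjusted p = 0.0761 with an estimated correlation). Ribosomal protein genes (21 of 31 higher, median 0.71), oxidative phosphorylation (median 0.31), replication-dependent histones (4 of 6 higher) and G2/M genes (17 higher and 1 lower of 51) lost their calls (adjusted p = 0.406, 0.406, 0.143 and 0.200 with an estimated correlation). With quantile normalization the oxidative phosphorylation median was -0.0099. In limma 4025 genes passed, 1638 higher and 2387 lower. With the hepatocyte marker mean of each array as a covariate, a choice made after seeing the data, 212 passed, 143 higher and 69 lower.

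After 48 h (2 against 3 arrays) most of the E2F-regulated genes were lower in the WT cells and interferon genes were higher. Of the 56 E2F genes 47 fell and 1 rose (48 and 1 adjusted over the list alone; median -0.96, adjusted p = 0.0232 with an estimated correlation), Tyms by 7.66-fold, Ccne1 by 4.68-fold and Uhrf1 by 3.05-fold. In the G2/M list 33 of 51 fell and 3 rose, Racgap1 by 2.64-fold (adjusted p = 0.151 with an estimated correlation). Of 25 repair genes 19 fell and 0 rose, Brca1 by 2.57-fold (adjusted p = 0.225 with an estimated correlation). All 27 interferon response genes rose (median 3.43, adjusted p = 0.0232 with an estimated correlation), Ifit1 by 353-fold and Oasl2 by 161-fold. Neutrophil markers rose in 17 of 18 cases and fell in 0, with Chil3 at 20.1-fold, Mmp8 at 9.58-fold and Ltf at 6.32-fold (adjusted p = 0.123 with an estimated correlation). Megakaryocyte markers rose in 15 of 21 and fell in 0, Plek by 5.14-fold and Pf4 by 2.92-fold (adjusted p = 0.175 with an estimated correlation). Macrophage markers split into 15 higher, such as Gpnmb (58.7-fold) and Cybb (7.63-fold), and 8 lower of 26 (adjusted p = 0.433 with an estimated correlation). Of the mast cell markers 6 of 8 rose and 1 fell (adjusted p = 0.274 with an estimated correlation). The counts adjusted over the list alone were 17 and 0, 15 and 0, 17 and 8, and 7 and 1 for these 4 lists in turn.

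Hepatocyte markers stayed low at 48 h (25 of 27 lower, median -5.05, adjusted p = 0.0952 with an estimated correlation), with Serpina6 421-fold and Apoa1 136-fold below 0 h. The p53 targets rose in 21 of 26 cases and fell in 3 (21 and 3 adjusted over the list alone; adjusted p = 0.00423 with an estimated correlation), Cdkn1a by 115-fold. Late erythroid clearance genes rose in 21 of 27 cases with 1 lower (22 and 1 adjusted over the list alone; adjusted p = 0.0154 with an estimated correlation), Sqstm1 by 8.01-fold and Gabarap by 4.73-fold. Ddit3 was 22.5-fold and Jun 33.9-fold higher. The unfolded protein and integrated stress list had 11 higher and 6 lower of 26 (adjusted p = 0.0334 with an estimated correlation). Epor (6.38-fold) and Tfr2, a partner of the erythropoietin receptor (7.86-fold), fell. So did the cholesterol enzymes Dhcr7 (9.22-fold) and Cyp51 (2.24-fold), with 11 of 20 in that list lower and 1 higher (adjusted p = 0.290 with an estimated correlation). The same held for the mitochondrial regulators Tfam (2.16-fold) and Nrf1 (2.72-fold), with 12 of 27 in that list lower and 2 higher (adjusted p = 0.327 with an estimated correlation). In limma 5432 genes passed, 2178 higher and 3254 lower. The median log2 change of all tested genes was -0.16, so changes of that size and smaller are within the shift of the whole distribution. With the hepatocyte marker mean as a covariate 1240 passed, 693 higher and 547 lower. The ribosomal protein median of 0.39 (adjusted p = 0.599 with an estimated correlation) became -0.087 with quantile normalization.

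The Rb1KO cells went through the same time course on separate arrays (5, 4 and 2 at 0, 24 and 48 h). At 24 h Serpina6 was 353-fold and Apoa1 212-fold lower, and Cdkn1a was 38.4-fold and Dleu2 15.7-fold higher. Ifit1 rose by 5.65 ± 0.29 (SE) on the log2 scale. At 48 h Cdkn1a was 42.8-fold, Ifit1 126-fold and P2rx7 57.5-fold higher, and Serpina6 was 205-fold and Apoa1 340-fold lower. Rb1 itself was 1.74-fold higher at 24 h and 2.30-fold higher at 48 h (log2 1.20 ± 0.20 SE, limma adjusted p = 3.81e-05). Hepatocyte markers fell in 27 of 27 cases at 24 h (adjusted p = 0.0525 with an estimated correlation), and interferon genes rose in 26 of 27 (adjusted p = 0.0447 with an estimated correlation) and in 27 of 27 at 48 h (adjusted p = 0.0357 with an estimated correlation). In limma 5568 genes passed at 24 h, 2227 higher and 3341 lower, and 5179 at 48 h, 2233 higher and 2946 lower. With the hepatocyte marker mean as a covariate the counts were 183 (113 higher and 70 lower) and 669 (418 and 251). Of the 4025 genes past the threshold in WT at 24 h, 3383 also passed in Rb1KO, 3371 of them in the same direction. Of these 1285 were higher and 2086 lower, against 334.2 and 730.6 for independent lists. At 48 h 4011 passed in both, 3953 in the same direction. In the 16 comparisons 0 set calls were made for glycolysis, hypoxia targets, apoptosis regulators, embryonic globins and lymphoid markers.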

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

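Of the tests below, the counts over other splits of the samples, the test of heat or handling stress, and those of intact cells and of a remaining Rb1 transcript were chosen after the results were seen; the other tests were set down before their result was known. The criterion of the stress test was reworded after its value was seen, because its genes moved both ways.

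The difference between Rb1KO and WT arrays changed with culture time for 90 genes from 0 h to 24 h and for 380 genes from 0 h to 48 h, by the interaction test in limma. At 24 h Dleu2 (log2 2.99) and Apold1 (2.56) had a larger difference than at 0 h, and Fasl (-3.33), Ackr3 (-3.16) and Cish (-1.19) a lower one. At 48 h the values were 2.36 for Tyms, 1.79 for Ccne1, 1.68 for Asf1b, 1.61 for Racgap1, 1.48 for Slbp, 3.55 for P2rx7, 2.09 for Icam4, 1.30 for Rb1, -1.43 for Cdkn1a, -1.47 for Trp53inp1, -1.53 for Bbc3 and -2.01 for Cish. In all 4 lists passed this test with an estimated correlation, with medians of 0.72 for the E2F list, 0.52 for G2/M genes, -0.40 for p53 targets and -0.35 for the unfolded protein and integrated stress response. Without Rb1KO 48 h replicate 2 the 380 became 128, without WT 48 h replicate 2 it became 197, and without WT 24 h replicate 2 the 90 became 44.

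The first pattern is the Rb1 signal in arrays labelled Rb1KO, which came close to WT at 48 h. Unequal scaling of the arrays is argued against: with quantile normalization the 48 h interaction of Rb1 was 1.497 ± 0.29 (SE), not below the deposited-scale value of 1.30. A rising share of cells with an intact Rb1 gene could account for it and cannot be told apart from the rest, because the E2F list's difference grew over the same time (interaction median 0.72), which such a share would work against but which a growing effect per cell may outweigh. A transcript that the altered allele still makes, and that the probe set reads, also stays open: Rb1 rose by 1.20 from 0 h to 48 h within Rb1KO, and where the probe set lies against the altered part is not given in the sources used here.

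The second pattern is the set of 109 genes that differed between DKO and Rb1KO arrays. Sex is confounded with genotype, since all 4 DKO arrays and 3 of 11 Rb1KO arrays had Y-linked signal, and 4 genes passed with Y-linked signal as a covariate. For the 104 genes outside X and Y, Rb1KO arrays with Y-linked signal differed from the other Rb1KO arrays by a signed median of 0.073 (SD over 40 splits 0.054). The DKO difference had a median size of 0.60. These values met the criterion set against sex but cannot decide. The 104 genes were called with a spread that includes the same Rb1KO arrays, so genes that follow sex were less likely to be called. Sex stays open for them. For the 5 genes on X or Y no such test was run. Chance cannot be excluded for the count, as given below, so a biological effect of p107 loss in the absence of Rb1 may or may not underlie these genes.

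The third pattern is the rise of Hspa1a and Hspa1b in Rb1KO arrays at every culture time. Both were also higher in DKO than in WT over the culture times, and neither passed in p107KO against WT. Heat or handling stress could raise them and cannot be told apart from an effect of genotype: of the 12 other heat shock genes 2 rose and 3 fell, and their median of -0.0083 (SE over genes 0.12) decides nothing because they moved both ways. A segment of another strain beside the altered Rb1 gene is argued against, since both genes lie on chromosome 17 and Rb1 on chromosome 14 in GRCm38.p6. An effect of Rb1 loss on these genes likely needs arrays from separately handled litters to be tested.

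Labels were reassigned among the arrays of the groups compared, between genotypes within each culture time or, for Rb1KO at 24 h against 0 h, between these 2 times. This asked whether other groupings of the arrays give as many genes past the threshold. For Rb1KO against WT at 0 h only the real split of 56 gave 67 genes or more, and the highest other gave 21. For Rb1KO against WT over the culture times 1 of 100 splits, the real one, gave 2062, and the highest other 1478. For Rb1KO at 24 h against 0 h 1 of 100 gave 5568, and the highest other 4301. For DKO against WT 1 of 90 gave 1457, and the highest other 1122. Splits that kept both lone DKO arrays, of 24 h and 48 h, in place gave 889 or more, and all others at most 64. The DKO count thus follows these lone arrays, so it cannot tell chance or an odd array from genotype. For these 4 counts the share of splits that reached the real count was under 0.05. For the Rb1KO counts that argues against chance only if the arrays are independent samples, which the labels do not state. For Rb1KO against WT at 0 h the share is under 0.05 only past the adjusted threshold. At an unadjusted p under 0.05, 11 of 56 splits gave the real 734 or more, the highest other 1280. Chance is not excluded for DKO against Rb1KO (5 of 100 splits gave 109 or more, the highest other 291) nor for p107KO against WT (10 of 100 gave 2 or more, the highest other 10). For the interaction of both genotypes the real count is 0, so all 100 of 100 splits reach it and the count decides nothing. At an unadjusted p under 0.05, 65 of 100 gave the real 495 or more. The highest other count past the threshold was 1017. These splits mixed all 4 genotypes within each culture time, so the Rb1 difference itself could enter the reassigned interaction. They therefore give no measure of chance for the interaction at either threshold.

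Single arrays lay far from the rest of their group in 13 of 198 sets of values tested in the Rb1KO groups at 0 h and 24 h (6.57%), where chance alone gives about 1 in 20. Rb1KO 0 h replicate 5 stood apart on the log2 scale for Cdk1 (12.69, others 12.90 to 12.96), Dleu2 (9.91, others 9.24 to 9.38), H2ax (13.45, others 13.99 to 14.08), Icam4 (13.12, others 13.70 to 13.85) and Xk (8.86, others 9.49 to 9.57). Rb1KO 0 h replicate 4 had 1.92% of its total signal in the 20 brightest probe sets (others 2.25% to 2.36%) and a low mean of replication-dependent histones (9.27, others 9.72 to 9.75). Rb1KO 0 h replicate 3 was low for Tcp11l2 (10.84, others 11.21 to 11.28). In Rb1KO 24 h replicate 1 the means of hepatocyte markers (8.06, others 7.28 to 7.40) and lymphoid markers (8.26, others 7.42 to 7.54) and the gene Spn (9.65, others 9.03 to 9.09) were high. Otud1 was low in Rb1KO 24 h replicate 2 (9.80, others 9.99 to 10.02) and Xk in replicate 4 (8.98, others 9.78 to 9.94).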

How the results depend on the processing

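The settings without the 9 arrays with Y-linked signal, without the 48 h arrays, without the 4 arrays apart (Rb1KO 0 h replicate 5 and replicate 1 of Rb1KO, p107KO and DKO at 24 h), with Y-linked signal as a covariate and with the hepatocyte marker mean as a covariate were chosen after seeing the data. All values are counts of genes past the threshold unless said otherwise, and apart from the settings' own construction (fewer arrays, or a covariate that moves with the groups) the cause was not tested. For the 16 comparisons fixed before the data were examined, counts within 1.5 times the main one are not listed. The targeted genes kept their direction and side of the threshold with pseudocounts of 1. None of the 4 arrays apart belongs to Rb1KO against WT at 48 h or to DKO against WT at 0 h. Without them those counts changed only with the estimated spread. The median SE fell from 0.277 to 0.235 and from 0.253 to 0.215 in these comparisons.

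Without the 9 arrays with Y-linked signal the counts were 1032, 27, 538 and 297 for Rb1KO against WT over time and at 0, 24 and 48 h, 2 for p107KO against WT at 0 h, 3452 for Rb1KO at 48 h against 0 h, and 28 and 42 for the interactions at 24 h and 48 h. DKO could not be fitted. Without the 48 h arrays they were 685 for Rb1KO and 456 for DKO against WT. With only the arrays of the groups compared they were 32, 273 and 595 for Rb1KO against WT at 0, 24 and 48 h, 6 and 4 for p107KO over time and at 0 h, 2278 and 149 for DKO over time and at 0 h, and 18 for DKO against Rb1KO. The 24 h interaction gave 55. Array weights gave 166 for Rb1KO at 0 h, 9 for p107KO, 2242 and 392 for DKO over time and at 0 h, 689 for DKO against Rb1KO and 196 for the 24 h interaction. Without the 4 arrays apart the counts were 1335 and 1720 for Rb1KO at 24 and 48 h, 7 for p107KO, 53 for DKO at 0 h, 5 for DKO against Rb1KO, and 168 and 700 for the interactions. Y-linked signal as a covariate gave 609 and 9 for DKO over time and at 0 h and 4 for DKO against Rb1KO, and turned Xist to 0.97 on the log2 scale. The hepatocyte marker mean gave 6 for p107KO, 212 and 1240 for WT at 24 and 48 h against 0 h, 183 and 669 for Rb1KO. It turned Fgg to 2.54, Apoa1 to 0.26 and C1qa to 1.76 in WT at 24 h. The mean over probe sets gave 1 for p107KO and turned Rb1 at 24 h to 0.048. Quantile normalization gave 44 for DKO at 0 h, split DKO against Rb1KO into 48 higher and 59 lower where the deposited scale gave 65 and 44, and turned the medians of oxidative phosphorylation to -0.0099 and -0.051 in WT and Rb1KO at 24 h and of ribosomal proteins to -0.087 in WT at 48 h. No filter gave 51 for DKO against Rb1KO, and a pseudocount of 1 gave 1 for the interaction of both genotypes.

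Replicate numbers are shared between groups and were not taken to pair the arrays. Deviations of 76 same-numbered pairs correlated with a median of 0.024 (-0.17 to 0.42), 19 of them over 0.1, and those of 175 other pairs with a median of -0.018, 22 over 0.1. The 2 arrays of a group of 2 deviate by equal and opposite amounts, so the same-numbered and other pairs are not independent. Same-numbered pairs within 1 culture time ran from -0.16 to 0.42 at 0 h and from 0.023 to 0.32 at 24 h, and were at 0.22 at 48 h. In all 12 of 24 arrays correlated best with an array of their own number, and 3 of 9 combinations of genotype and number mix arrays with and without Y-linked signal. Whether some numbers mark a shared preparation stays open. With the replicate number as a block the counts were 38 for Rb1KO against WT at 0 h, 5 for p107KO against WT and 212 for DKO against Rb1KO, and the block moved no other count by over 1.5 times.

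Leaving out each array in turn gave ranges of 1329 to 2372 for Rb1KO against WT over time, 26 to 61 at 0 h, 297 to 891 at 24 h, and 477 to 1000 at 48 h. Ranges were 2 to 15 and 1 to 2 for p107KO over time and at 0 h, 448 to 1438 and 7 to 15 for DKO over time and at 0 h, and 2 to 256 for DKO against Rb1KO. They were 0 to 1 for the interaction of both genotypes, 44 to 110 and 128 to 458 for the interactions with time, 2809 to 3686 and 3945 to 4908 for WT at 24 and 48 h against 0 h, and 5171 to 5624 and 3910 to 5337 for Rb1KO. For the comparisons added after the data were seen, the 764 of DKO against p107KO became 217 without p107KO 48 h replicate 1, 222 and 362 without DKO 48 h or 24 h replicate 1, 226 without the 48 h arrays, 496 with Y-linked signal and 405 with the hepatocyte marker mean as a covariate, and 1279 with array weights. At 48 h against 24 h the 2755 of WT became 1400 without WT 24 h replicate 2 and 1694 without WT 48 h replicate 1. The 2289 of Rb1KO became 745 without Rb1KO 48 h replicate 1, 1159 with only these groups and 1379 without the 9 arrays with Y-linked signal. A lone array left in a group is assumed to vary like those of the other groups. For named genes, 2708 values under other settings kept their call, 163 lost it and 5 changed sign; leaving out an array kept 1978 and lost 147. Of 170 list calls, 44 held and 126 were lost with an estimated correlation, 141 held with quantile normalization, 158 with the mean over probe sets, 151 with the block and 157 with the Y-linked covariate. No list call was recomputed with an array left out. The covariate of the actin 3' to 5' ratio was not run, as control probe sets were not used here. Signals near the floor limit dim genes, and DKO and p107KO groups with 1 array limit their 24 and 48 h values.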

Other observations

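In the comparison of 48 h with 24 h, added after the data were seen, most of the E2F-regulated genes fell in WT cells. Of the 56 E2F genes 45 fell and 0 rose (51 and 0 adjusted over the list alone; median -1.03, adjusted p = 0.00127 with an estimated correlation). Of the 51 G2/M genes 42 fell and 0 rose (45 and 0 adjusted over the list alone; median -0.98, adjusted p = 0.00365 with an estimated correlation). In Rb1KO the same lists had 19 of 56 and 30 of 51 genes lower and 0 higher (24 and 34 adjusted over the list alone), with medians of -0.42 and -0.59 (adjusted p = 0.0339 for each with an estimated correlation). Megakaryocyte markers rose in 20 of 21 cases in WT (median 1.65, adjusted p = 0.0548 with an estimated correlation) and in 19 of 21 in Rb1KO (median 1.57, adjusted p = 0.0499 with an estimated correlation). Stem and progenitor markers rose in 12 of 20 cases in WT and 10 of 20 in Rb1KO, with 0 lower in both (adjusted p = 0.0639 and 0.0719 with an estimated correlation). Heme and iron genes fell in 10 of 25 cases and rose in 1 in both genotypes (adjusted p = 0.0639 in WT and 0.0883 in Rb1KO with an estimated correlation). In limma 2755 genes passed in WT, 1440 higher and 1315 lower, and 2289 in Rb1KO, 1463 higher and 826 lower. The direction of the WT majority depends on the processing, with 1250 higher and 1364 lower under quantile normalization and 1040 and 1275 with the lowest 60% left out. The WT count was 1400 without WT 24 h replicate 2 (680 higher and 720 lower) and 1694 without WT 48 h replicate 1 (790 and 904). The Rb1KO count was 745 without Rb1KO 48 h replicate 1, 1159 with only these groups and 1379 without the 9 arrays with Y-linked signal.

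Both tests of the neighbourhood of the altered genes were set down before their results were seen. If a segment of another strain had travelled with the altered Rb1 gene, the 50 tested genes on either side could hold more calls in Rb1KO against WT. Of these 22 of 100 passed (22.0%) against 2039 of 10815 others (18.9%), a ratio of 1.17. Its upper 95% bound of 1.69 argues against a 2-fold excess (Fisher's exact test, two-sided, p = 0.441). Around Rbl1, 10 of 100 genes (10.0%) had an unadjusted p under 0.05 in p107KO against WT, against 697 of 10815 others (6.44%). The ratio was 1.55 with an upper bound of 2.81 (p = 0.151 by Fisher's exact test), so such a segment cannot be told apart from chance there. The neighbourhood of Rbl1 was not tested in the comparisons with DKO.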
